A study of Homo sapiens with 39 samples.

How the data were processed

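Values were read as deposited by the authors, whose notes name the RMA algorithm in Partek 6.5 for the Affymetrix HG-U133 Plus 2.0 arrays. The deposited table holds log2 signal, with values from 2.50 to 14.9 over 54675 probe sets and 39 arrays and array medians close to each other, so no further transformation or scaling was made for the main results. Raw intensity files were not used here, and the RMA version is not stated in the notes.

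The 62 control probe sets were set aside. Probe sets were named from the platform table (annotation year 2016), which lists 42892 with a symbol; 41091 carry exactly 1 symbol and were kept, while 1801 with several and 11721 with none were left out of the gene tests. Symbols were compared with the RefSeq reference for assembly GRCh38.p14 and none needed changing. Of 19775 genes, 10523 had several probe sets, and the one with the highest mean over all arrays stood for the gene. Genes above the 40th percentile of all values (4.88) on at least 3 arrays were tested, which left 15518.

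Groups were compared in R 4.3.3 with limma 3.58.1, as 1 linear model of 10 group means over all 39 arrays with moderated statistics, so all groups shared the estimate of spread. Each comparison was adjusted by the Benjamini-Hochberg method over all 15518 genes, and a gene counted as changed with an adjusted p under 0.05. The 16 comparisons were each dose against unexposed cultures at each time, the doses against each other at each time, each dose averaged over the 3 times, the change of the 10 µM effect between successive times, and unexposed cultures against 0 h. Cultures were treated as biological repeats, as the design names replicates 1 to 4; replicate 2 of 10 µM at 24 h was not part of the series as listed.

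Pairing by replicate number was checked by correlating, across genes, the deviations of arrays with the same number from their group means. Doses at 72 h were the only comparison in which all 4 pairs passed the minimum of 0.1 set beforehand (correlations 0.18 to 0.45), and elsewhere at most 2 pairs passed. There the replicate number was added as a block, which gave 4137 genes in the full model against 4058 without it. However, only 2 of the 4 arrays at 10 µM and 72 h correlated best with the 0.1 µM array of their own number. At 0.1 µM and 6 h all 4 did so with unexposed arrays (correlations 0.09 to 0.20). Whether replicate number marks paired cultures is therefore uncertain.

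Gene lists of 32 pathways and cell types were written before the data were examined. Shifts of each list against all other genes were tested with camera from limma with its preset inter-gene correlation of 0.01, and adjusted over lists and the 6 comparisons of exposed and unexposed cultures together, and over lists and the 3 unexposed time comparisons together. Direct comparisons of doses and averages were adjusted over the lists in each. Counts "over the list alone" repeat the gene adjustment within the list. The same test with a correlation estimated from the data, and fry, were alternatives.

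The text names genes by a rule set beforehand. It took the 10 largest rises and 10 largest falls among genes past the threshold whose groups of arrays did not overlap, for exposed against unexposed cultures and for unexposed cultures at 72 h. It took 5 of each for the other unexposed times and for differences between doses or times. It added up to 4 genes with the smallest p from each list, and ACHE and BCHE throughout. In 22 of 1602 pairs of named gene and comparison another probe set of the gene passed the threshold in the opposite direction, among 829 pairs with other probe sets to compare. These concerned INPP4B, LDB3, IDI1, COX7B, MYLK, TEK and KRT7 at 10 µM and 6 h, and 15 further pairs. Other probe sets that passed in neither direction are not in this count. At 10 µM and 24 h, for example, the other probe sets of PKM (1), ASPM (2) and CCNB2 (1) did not pass. Those of RRM2 (1) and MYLK (2) passed in the same direction.

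RNA quality was taken as the mean of the 3′ minus 5′ log2 signal of the ACTB and GAPDH control probe sets, and compared by exact permutation of arrays. Later unexposed cultures were compared with 0 h for both array measures after the data were seen. The interquartile range of each array was compared in the same way, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Correlations between doses were set beside simulations with shared controls and no common effect, and beside comparisons of each dose with a different pair of control arrays. Overlaps were counted in the same way after the data were seen, and set beside 100 simulations of noise with shared controls in which as many genes were called.

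The model was tested on simulated data with 200 changed genes among 15518, 100 at each of 1.5- and 2-fold, and a 30-gene list shifted by 0.3. For 10 µM at 6 h it recovered 96% and 100% of them with 16 false calls. For doses at 72 h the shares were 96% and 100% with 9, and for the change of effect from 6 to 24 h 78% and 97% with 13. An unshifted list had p from 0.188 to 0.646 by camera over the comparisons tested. Simulated genes varied independently of each other, so this cannot show how the list test behaves for genes that vary together.

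Alternatives set beforehand were the mean of a gene's probe sets (14550 genes), all 35879 expressed probe sets, trended and robust variance, array weights, the arrays of the compared groups alone, leaving out each array, replicate number as a block, quantile normalization, median centring, no filter, and a 60th-percentile filter (6.18, 11917 genes). The array interquartile range as a covariate, leaving out 3 arrays with large deviations, the compared groups alone with a block, and leaving out single arrays from the RNA quality measure were added after the data were seen.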

Results

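Human iCell cardiomyocytes, a heart muscle cell preparation differentiated from the WA09 embryonic stem cell line, were exposed for 1 h to VX, an organophosphorus nerve agent that inactivates acetylcholinesterase. The doses were 0.1 and 10 µM, both set below the lethal range, and unexposed cultures served as controls. Messenger RNA was measured on 39 Affymetrix arrays, 1 per culture. Unexposed cultures were sampled at 0, 6, 24 and 72 h and exposed cultures at 6, 24 and 72 h. Each of the 10 groups held 4 cultures, except 10 µM at 24 h with 3, and these numbers limit the precision of every value. After filtering, 15518 genes were tested. Changes are differences of log2 signal with their standard error (SE), and group levels are means with their standard deviation (SD). The p-values and SEs of single genes rest on a spread between cultures that was estimated for each gene over all 10 groups. They overstate precision in groups whose cultures varied more than the others. The p-values of lists with the preset correlation compare a list with all other genes. They take the correlation between genes as fixed and do not measure how a list varied between cultures. "Rose" and "fell" are used of genes with an adjusted p under 0.05. Levels under 4.88, the value of the expression filter, lie near background and the size of a change into or out of that range is uncertain; 1 of the groups compared lay there for ECM2 and GSG1 (unexposed, 0 h), INHBE and PRDM16 (exposed, 6 h), PTGS2 and H2BC4 (unexposed, 6 h), PURPL (10 µM, 6 h) and XIRP2 (unexposed, 72 h). The 16 comparisons, the gene lists and their main tests were chosen before the data were examined, and models added later are named as such.

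**Figure D1:**
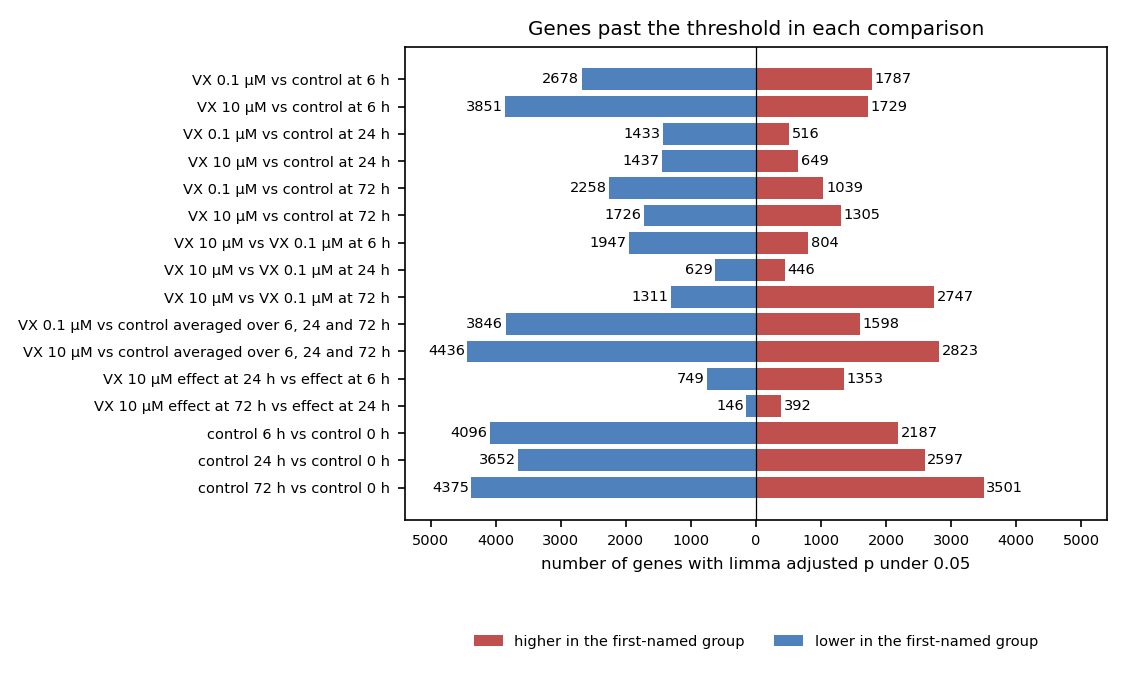
Number of genes higher (to the right) and lower (to the left) past an adjusted p of 0.05 in each of the 16 comparisons, of 15518 tested. The unexposed time courses, the averages over time and 10 µM at 6 h held the largest counts, and the balance of higher and lower calls in exposed cultures depended on array scaling, as given in the text.

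The unexposed cultures show how expression differed between times without exposure. Against 0 h, 6283 genes changed at 6 h (2187 higher, 4096 lower), 6249 at 24 h (2597 and 3652) and 7876 at 72 h (3501 and 4375). In 46.6%, 44% and 53.7% of all tested genes the groups of arrays did not overlap, where 2.86% would fall so by chance. At 6 h the largest rises included ECM2, a matrix protein (log2 change 3.23 ± 0.17 SE, adjusted p = 1.56e-16; 4.41 ± 0.14 SD at 0 h and 7.64 ± 0.17 at 6 h, n = 4 each). KRT7, an epithelial keratin, rose by 3.04 ± 0.15 and OXTR, the oxytocin receptor, by 2.94 ± 0.14. TXNIP, a glucose-responsive thioredoxin inhibitor, fell by 1.64 ± 0.11 and PDK4, a brake on pyruvate oxidation, by 1.77 ± 0.20. For each gene named among the largest changes of this and the following comparisons against controls, every array of one group lay beyond every array of the other.

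At 72 h CASQ2, the calcium buffer of the sarcoplasmic reticulum, had risen from 6.48 ± 0.15 to 10.26 ± 0.09 (log2 change 3.78 ± 0.13, adjusted p = 8.12e-22). GSG1, a membrane protein best known from germ cells, rose by 4.34 ± 0.14 and LUM, the collagen-binding lumican, by 3.86 ± 0.15. The transcription regulators ID1 and ID3, which act downstream of BMP signalling, fell by 2.56 ± 0.18 and 1.76. In the sarcomere list 12 of 23 genes rose, among them MYL2 (1.81), LMOD2 (2.14) and TNNI1 (1.80), 5 fell and 6 did not pass. Adjusted over the list alone the counts were 13 and 5, and the list median was 0.12 (adjusted p = 0.00157; adjusted p = 0.402 with an estimated correlation).

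Of the 34 genes of the extracellular matrix and TGF-beta list, 29 rose and 1 fell at 6 h, and 4 did not pass. They included TGFBI (2.46), INHBA (1.90) and FN1 (1.01). The counts over the list alone were the same, with a list median of 0.58 (adjusted p = 9.49e-23, and adjusted p = 0.000151 with an estimated correlation). It stayed higher at 24 h (25 rose, 2 fell; median 0.56) and at 72 h (23 rose, 7 fell; median 0.74). Of 44 cell cycle genes, 37 rose and 2 fell at 6 h, with TTK at 1.37 and ASPM at 1.35. The list median was 0.81 (adjusted p = 4.99e-19; adjusted p = 0.113 with an estimated correlation), and adjusted over the list alone 38 rose and 2 fell.

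The unfolded protein and integrated stress response list holds chaperone and protein degradation genes as well as genes of amino acid supply. In unexposed cultures at 6 h, of 31 measured, 24 rose, 0 fell and 7 did not pass, or 25 and 0 over the list alone. SLC7A11, the cystine importer, rose by 1.47 and PSAT1, of serine synthesis, by 1.00. The median was 0.33 (adjusted p = 5.72e-11; adjusted p = 0.185 with an estimated correlation). Of the histone genes, 8 fell and 1 rose at 6 h (median −0.64, adjusted p = 0.000891; adjusted p = 0.161 with an estimated correlation). Among 20 cholesterol synthesis genes, 14 rose at 24 h, or 15 over the list alone, including INSIG1 (1.39) and ACAT2 (1.06). That list's median was 0.43 (adjusted p = 9.59e-09; adjusted p = 0.0522 with an estimated correlation). At 72 h, 15 of 25 immediate early genes fell and 1 rose, DUSP6 by −1.74 among them (median −0.42, adjusted p = 0.000191; adjusted p = 0.195 with an estimated correlation). In the interferon list 12 of 21 genes rose, IFIT1 by 2.02 (median 0.26, adjusted p = 0.00157; adjusted p = 0.143 with an estimated correlation). All 3 comparisons shared the 0 h arrays, which also differed from later ones in array spread and, against 24 and 72 h, in the RNA quality measure. The spread went from an interquartile range of 4.48 ± 0.01 at 0 h to 4.36 ± 0.04, 4.37 ± 0.03 and 4.37 ± 0.05 (exact permutation p = 0.0286 each), and with it as a covariate 5771, 5695 and 7769 genes changed. The 3′ minus 5′ signal of the ACTB and GAPDH control probe sets went from 0.62 ± 0.05 to 0.72 ± 0.11 (exact permutation p = 0.143), 0.76 ± 0.10 and 0.75 ± 0.05 (exact permutation p = 0.0286 each). At 24 h ACTB alone differed by 0.21 (exact permutation p = 0.0571) and GAPDH alone by 0.08 (exact permutation p = 0.0857). At 72 h they differed by 0.23 (exact permutation p = 0.0286) and 0.04 (exact permutation p = 0.2). None of these p-values was adjusted over the 3 comparisons.

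The 6 h comparison at 0.1 µM asks what the low dose changed soon after washing. There, 4465 genes changed (1787 higher, 2678 lower), 603 of them by 1.5-fold or more. Groups did not overlap in 33.3% of tested genes, against 2.86% by chance. EGR3, an immediate early transcription factor, rose from 6.24 ± 0.20 to 8.31 ± 0.09 (log2 change 2.07 ± 0.14, adjusted p = 2.67e-13; n = 4 each). PDCD4, which restrains translation initiation, rose by 1.78 ± 0.11, PTGER4, a prostaglandin E2 receptor, by 1.65 ± 0.15, and FGF18, a secreted growth factor, by 1.62 ± 0.12. ECM2 fell from 7.64 to 5.16 (−2.49 ± 0.17, adjusted p = 3.72e-13). INHBE, an inhibin subunit induced by stress signalling, fell by 2.17 ± 0.23, and PRDM16, a chromatin regulator, by 1.92 ± 0.11. Among the list genes, PTGS2, the inducible cyclooxygenase, rose by 1.46 (adjusted p = 2.16e-07) and CASQ2 fell by 0.98.

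Of the 31 genes of the unfolded protein and integrated stress response list, 28 fell and 0 rose at 0.1 µM, and 3 did not pass. SLC7A11 fell from 9.99 ± 0.05 to 8.24 ± 0.21, GDF15, a stress-induced cytokine, by 1.58, and MTHFD2, of mitochondrial folate metabolism, by 1.00. Adjusted over the list alone 29 fell and 1 rose, and the median was −0.53 (adjusted p = 1.33e-16; adjusted p = 0.278 with an estimated correlation). In the cell cycle list 25 of 44 genes fell, including TPX2 (−0.90) and CDC6 (−1.04), and 0 rose. The counts over the list alone were 28 and 1 (median −0.41, adjusted p = 6.47e-09; adjusted p = 0.485 with an estimated correlation). Matrix genes fell in 16 cases of 34, or 17 over the list alone, with TGFBI at −1.32 and COL6A3 at −1.12 (median −0.18, adjusted p = 0.000176; adjusted p = 0.278 with an estimated correlation). Immediate early genes were higher as a list, with 7 of 25 rising and 1 falling, or 8 and 1 over the list alone; FOSB rose by 0.58 and ZFP36 by 0.52. Their median was 0.15 (adjusted p = 0.00545; adjusted p = 0.485 with an estimated correlation).

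Cardiac transcription factors rose in 6 of 17 cases and fell in 1, or 7 and 1 over the list alone, with TBX5 at 0.46 and SRF at 0.33. The median was 0.10 (adjusted p = 0.0196; adjusted p = 0.505 with an estimated correlation). Of 11 histone genes 5 rose, H2BC4 by 0.54 and H4C8 by 0.41, or 7 over the list alone (median 0.24, adjusted p = 0.0186; adjusted p = 0.441 with an estimated correlation). Centring each array on its median turned the balance of all calls to 2468 higher and 2073 lower.

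The 6 h comparison at 10 µM asks the same of the high dose. Here 5580 genes changed (1729 higher, 3851 lower), 646 by 1.5-fold or more, and groups did not overlap in 37.9% of tested genes against 2.86% by chance. EGR3 rose to 8.05 (log2 change 1.81 ± 0.14, adjusted p = 5.3e-12), ZNF365, a zinc finger protein of the DNA damage response, by 1.53 ± 0.10, and CCL4, a chemokine, by 1.09 ± 0.11. GDF15 fell from 10.71 ± 0.07 to 8.63 ± 0.31 (−2.09 ± 0.23, adjusted p = 6.07e-09). ECM2 fell by 2.51 ± 0.17, INHBE by 2.24 ± 0.23, PRDM16 by 2.04 ± 0.11 and CTH, which makes cysteine, by 1.72 ± 0.12. The signal of BCHE, butyrylcholinesterase, was lower by −0.59 ± 0.14 (adjusted p = 0.00136), but on every array at 6 h it lay under the filter value of 4.88, near background.

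In the stress response list 25 genes fell, 1 rose and 5 did not pass, or 27 and 1 over the list alone. SLC7A11 fell by 1.69 ± 0.11, TRIB3, a pseudokinase target of ATF4, by 1.39, and PSAT1 by 1.13. The median was −0.39 (adjusted p = 1.77e-09; adjusted p = 0.387 with an estimated correlation). Cell cycle genes fell in 22 of 44 cases and rose in 0, the same over the list alone, with ASPM at −1.21 and TTK at −1.04 (median −0.29, adjusted p = 0.0116; adjusted p = 0.785 with an estimated correlation). Immediate early genes rose in 11 cases and fell in 1, or 12 and 1 over the list alone, with SGK1 at 0.82 and FOSL1 at 0.66 (median 0.18, adjusted p = 8.19e-06; adjusted p = 0.278 with an estimated correlation). Inflammatory genes rose in 7 of 20 cases and fell in 1, LIF by 0.96 and TNFAIP3 by 0.63, with the same counts over the list alone. Their median was 0.04 (adjusted p = 0.0323; adjusted p = 0.278 with an estimated correlation).

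Sarcomere genes fell in 13 of 23 cases at 10 µM and rose in 0, the same over the list alone. MYL2, the ventricular regulatory light chain, fell by 0.76 and MYOM1, of the M-band, by 0.53. The median was −0.19 (adjusted p = 0.00213; adjusted p = 0.595 with an estimated correlation). Fatty acid oxidation genes fell in 17 of 29 cases and rose in 0, or 18 and 2 over the list alone, with the carnitine carrier SLC25A20 at −0.52 and PPARA at −0.41 (median −0.19, adjusted p = 0.0063; adjusted p = 0.505 with an estimated correlation). Matrix genes fell in 15 cases and rose in 3, but the list as a whole was not called (adjusted p = 0.137) and its median turned to 0.02 when arrays were centred. The balance of all calls became 2740 higher and 2610 lower after quantile normalization, 4926 and 2087 after centring, and 1351 and 2172 with each array's interquartile range as a covariate, a model added after the data were seen. Centring moved the median change of all genes by 0.133 here and by 0.119 at 0.1 µM and 72 h.

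**Figure D2:**
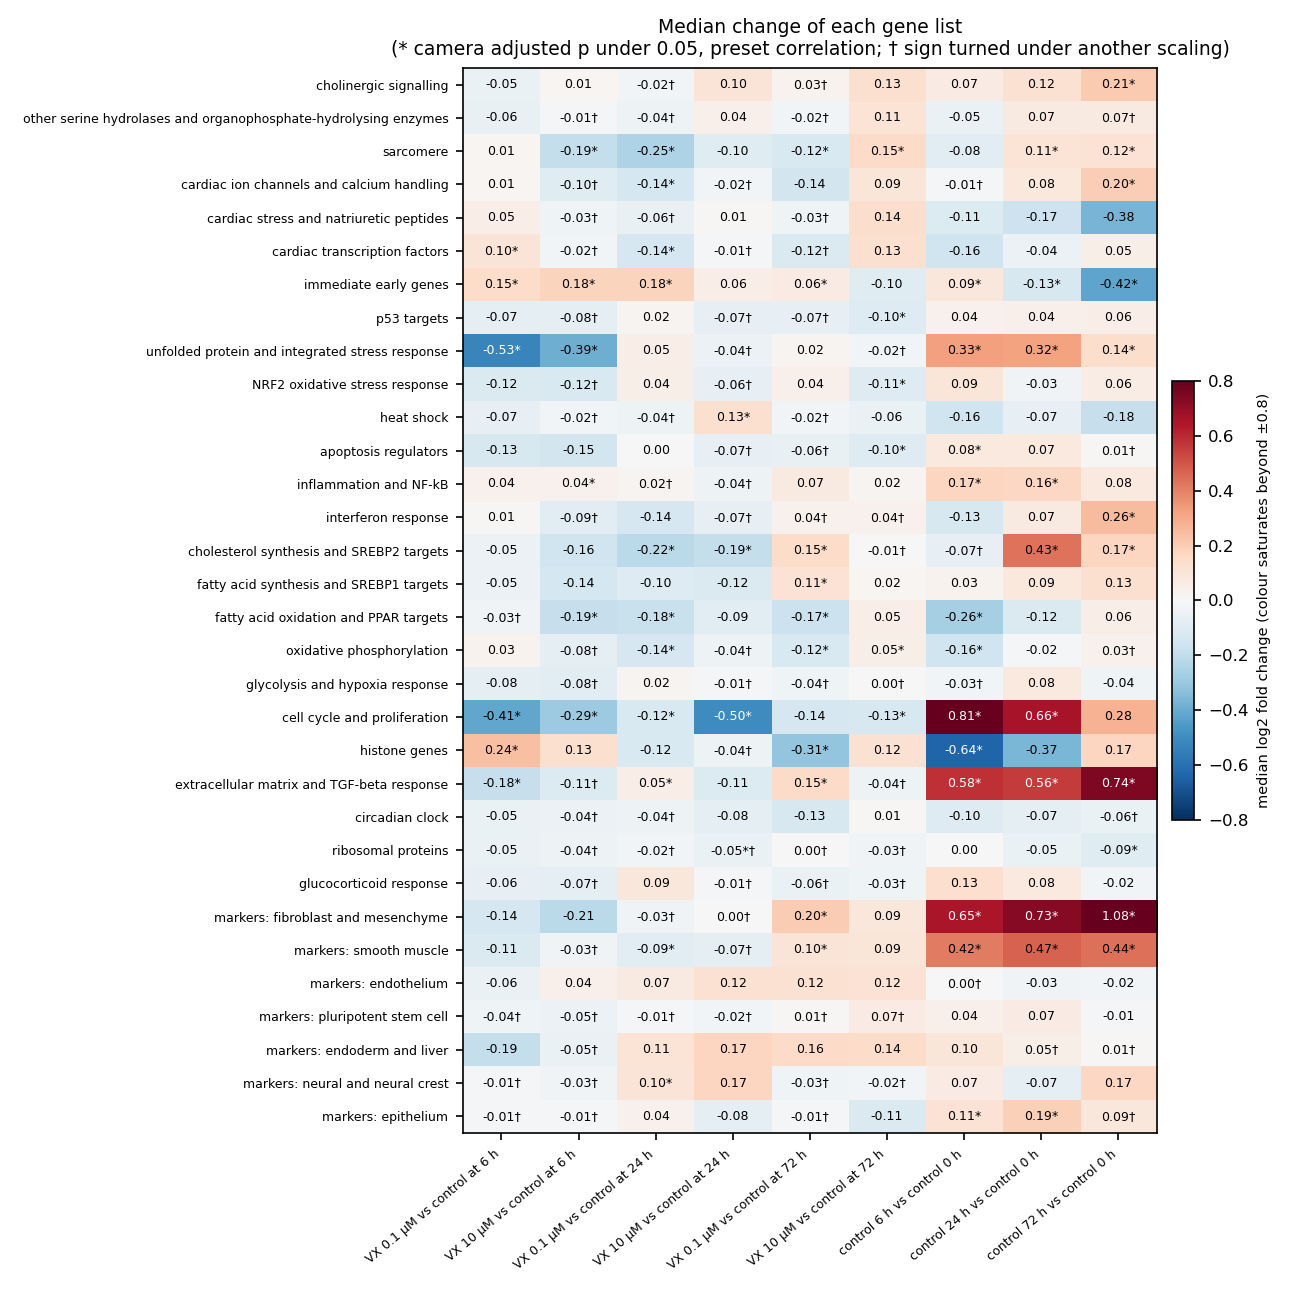
Median log2 change of each gene list (vertical) in each comparison of exposed and unexposed cultures and of unexposed cultures with 0 h (horizontal), n = 3 or 4 arrays per group. A star marks an adjusted p under 0.05 with a preset correlation, and a dagger marks a median whose sign turned under another scaling; the stress response and cell cycle lists were lower after either dose at 6 h and higher in unexposed cultures.

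Across genes, which are not independent replicates, the 6 h changes at the 2 doses correlated at 0.76. Sharing control arrays alone gave 0.5 in 100 simulations, and comparing each dose with different control arrays gave 0.67 (0.62 to 0.72 over 6 splits). The covariance was 0.0519, of which 0.00447 came from shared controls in simulation. Both doses raised 837 genes and lowered 2163, and 17 went opposite ways. Independent comparisons would share 199 and 665, and calls of the same number made of noise with shared controls alone would share 601 and 1403. With different control arrays for each dose 535 were raised and 1518 lowered by both, means over 6 splits, where independence gives 92 and 388. Against unexposed cultures at 0 h rather than 6 h, the stress response medians were −0.15 and −0.12 at 0.1 and 10 µM. The cell cycle medians were 0.28 and 0.39, with 18 genes higher and 2 lower, and 30 and 3. The matrix medians were 0.38 and 0.39, with 27 genes higher and 0 lower at each dose. Cell cycle and matrix genes thus stood above 0 h after exposure, and below unexposed cultures whose own medians rose by 0.81 and 0.58 by 6 h.

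The direct comparison of doses at 6 h tests where 10 µM differed from 0.1 µM. In all, 2751 genes differed (804 higher, 1947 lower at 10 µM). CALB2, a calcium-binding protein, was higher by 0.65 ± 0.10 (adjusted p = 0.000103) and PLAUR, the urokinase receptor, by 0.61 ± 0.12. ENPP5, a membrane phosphodiesterase family protein, was lower by −0.97 ± 0.18, and PURPL, a long noncoding RNA under p53 control, by −1.12 ± 0.23. Sarcomere genes were lower in 14 of 23 cases and higher in 0, or 16 and 0 over the list alone. They included TNNI3 (−0.67) and ACTN2 (−0.33), with a median of −0.22 (adjusted p = 1.96e-08; adjusted p = 0.338 with an estimated correlation). Cell cycle genes were higher in 5 of 44 cases, RRM2 by 0.37 and TPX2 by 0.36, and lower in 0 (median 0.14, adjusted p = 4.28e-05; adjusted p = 0.616 with an estimated correlation). Stress response genes were higher in 6 cases and lower in 1, or 6 and 2 over the list alone, with CHAC1 at 0.56 (median 0.10, adjusted p = 0.00206; adjusted p = 0.616 with an estimated correlation). The balance of calls was 1033 higher and 1120 lower after quantile normalization, 2170 and 840 after centring, and 291 and 421 with the interquartile range as a covariate.

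At 24 h the question is which changes were present a day after exposure. At 0.1 µM, 1949 genes changed (516 higher, 1433 lower), 97 by 1.5-fold or more, and groups did not overlap in 16.2% of tested genes against 2.86% by chance. CASQ2 fell from 9.08 ± 0.15 to 7.80 ± 0.32 (−1.28 ± 0.13, adjusted p = 3.71e-07). LMOD2, which elongates thin filaments, fell by 0.97 ± 0.13, KLHL41, a sarcomere-stabilizing protein, by 0.99 ± 0.16, and GJA5, the connexin of conducting cells, by 0.96. SPP1, the matrix cytokine osteopontin, rose by 0.88 ± 0.20 and THBD, thrombomodulin, by 0.76 ± 0.15.

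Sarcomere genes fell in 15 of 23 cases at 0.1 µM and 24 h and rose in 0, or 18 and 0 over the list alone, with TNNI1 at −0.90 and MYL2 at −0.71. The median was −0.25 (adjusted p = 7.46e-13; adjusted p = 0.244 with an estimated correlation). Oxidative phosphorylation genes fell in 18 of 33 cases and rose in 0, or 25 and 0 over the list alone, including NDUFA8 (−0.33) and UQCRC2 (−0.19). Their median was −0.14 (adjusted p = 3.33e-10; adjusted p = 0.338 with an estimated correlation). Fatty acid oxidation genes fell in 13 of 29 cases, or 15 over the list alone, ETFDH by 0.52 and FABP3 by 0.38 (median −0.18, adjusted p = 9.39e-06; adjusted p = 0.297 with an estimated correlation). Cholesterol synthesis genes fell in 9 of 20 cases, or 14 over the list alone, EBP by 0.41 and IDI1 by 0.37 (median −0.22, adjusted p = 2.55e-06; adjusted p = 0.278 with an estimated correlation).

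Ion channel and calcium handling genes fell in 9 of 25 cases at 0.1 µM and 24 h, or 11 over the list alone, TRDN by 0.80 (median −0.14, adjusted p = 0.00148; adjusted p = 0.338 with an estimated correlation). Immediate early genes rose in 6 of 25 cases, or 10 over the list alone, SGK1 by 0.56 and EGR3 by 0.48. Their median was 0.18 (adjusted p = 9.75e-08; adjusted p = 0.244 with an estimated correlation). Leaving out replicate 2 of the unexposed cultures at 24 h lowered the count of all genes to 1231. The balance of calls was 779 higher and 995 lower after quantile normalization, 1442 and 693 after centring, and 692 and 878 with the interquartile range as a covariate.

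At 10 µM and 24 h, with 3 exposed cultures, 2086 genes changed (649 higher, 1437 lower), 122 by 1.5-fold or more. Groups did not overlap in 28% of tested genes, against 5.71% by chance. GSG1 fell from 7.23 ± 0.16 to 5.89 ± 0.32 (−1.34 ± 0.15, adjusted p = 7.07e-07), and HMCN1, a basement membrane protein, by 0.93. The largest falls also included the kinetochore genes SPC25 (−1.11 ± 0.19) and KNL1 (−0.95 ± 0.14), and ASPM of the spindle poles (−0.91 ± 0.13). PKM, pyruvate kinase, rose by 0.71 ± 0.11 (adjusted p = 5.63e-05) and PPP2R1A, a phosphatase scaffold, by 0.64.

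Cell cycle genes fell in 30 of 44 cases at 10 µM and 24 h, rose in 0 and did not pass in 14, or fell in 32 over the list alone. BIRC5, survivin, of the apoptosis regulator list, fell by 0.85. In the cell cycle list CCNB2, a mitotic cyclin, fell by 0.89 and RRM2, of nucleotide synthesis, by 0.82. The median was −0.50 (adjusted p = 1.47e-18; adjusted p = 0.278 with an estimated correlation). Cholesterol synthesis genes fell in 9 of 20 cases, or 10 over the list alone, IDI1 by 0.44 and STARD4 by 0.33 (median −0.19, adjusted p = 0.000141; adjusted p = 0.385 with an estimated correlation). Heat shock genes rose in 6 of 16 cases, the same over the list alone, HSPB1 by 0.29 and HSPH1 by 0.22 (median 0.13, adjusted p = 0.00575; adjusted p = 0.338 with an estimated correlation). Ribosomal protein genes were lower as a list, with 5 of 34 falling and 1 rising, but their median of −0.05 turned to 0.02 under centring (adjusted p = 0.0217; adjusted p = 0.682 with an estimated correlation). The count of all genes was 1381 without unexposed replicate 4, 1296 without exposed replicate 3 and 636 without exposed replicate 4. The balance was 857 higher and 818 lower after quantile normalization, 1515 and 705 after centring, and 314 and 404 with the interquartile range as a covariate.

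Across genes, which are not independent replicates, the 24 h changes at the 2 doses correlated at 0.62. Shared controls alone gave 0.46 in simulation and split controls gave 0.47 (0.37 to 0.58), with a covariance of 0.0197 of which 0.00446 came from shared controls. Both doses raised 119 genes and lowered 540, and 7 went opposite ways. Independence would give 22 and 133, and noise with shared controls 113 and 417. With different control arrays for each dose the counts were 24 and 148, where independence gives 4 and 31.

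Between the doses at 24 h, 1075 genes differed (446 higher, 629 lower at 10 µM). GSTM4, a glutathione transferase, was higher by 0.78 ± 0.14 (adjusted p = 0.000942) and TNNI1, slow skeletal troponin I, by 0.68 ± 0.13. ASPM was lower by −0.78 ± 0.13 (adjusted p = 0.000755) and CCNE2, a cyclin of S-phase entry, by −0.78 ± 0.14. Cell cycle genes were lower in 20 of 44 cases and higher in 0, or 26 and 0 over the list alone, with RRM2 at −0.71 and CDC6 at −0.73. The median was −0.38 (adjusted p = 6.24e-17; adjusted p = 0.176 with an estimated correlation). Sarcomere genes were higher in 10 of 23 cases and lower in 0, or 12 and 0 over the list alone, MYL2 by 0.52 and MYL3 by 0.36 (median 0.15, adjusted p = 1.69e-09; adjusted p = 0.176 with an estimated correlation). Matrix genes were lower in 8 of 34 cases, or 11 over the list alone, INHBA by −0.51 (median −0.13, adjusted p = 2.54e-06; adjusted p = 0.176 with an estimated correlation). This comparison depended on the spread estimated from all groups: fitted on its 7 arrays alone it gave 25 genes. Without exposed replicate 3 at 10 µM it gave 199, and without replicate 4 it gave 695.

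**Figure D3:**
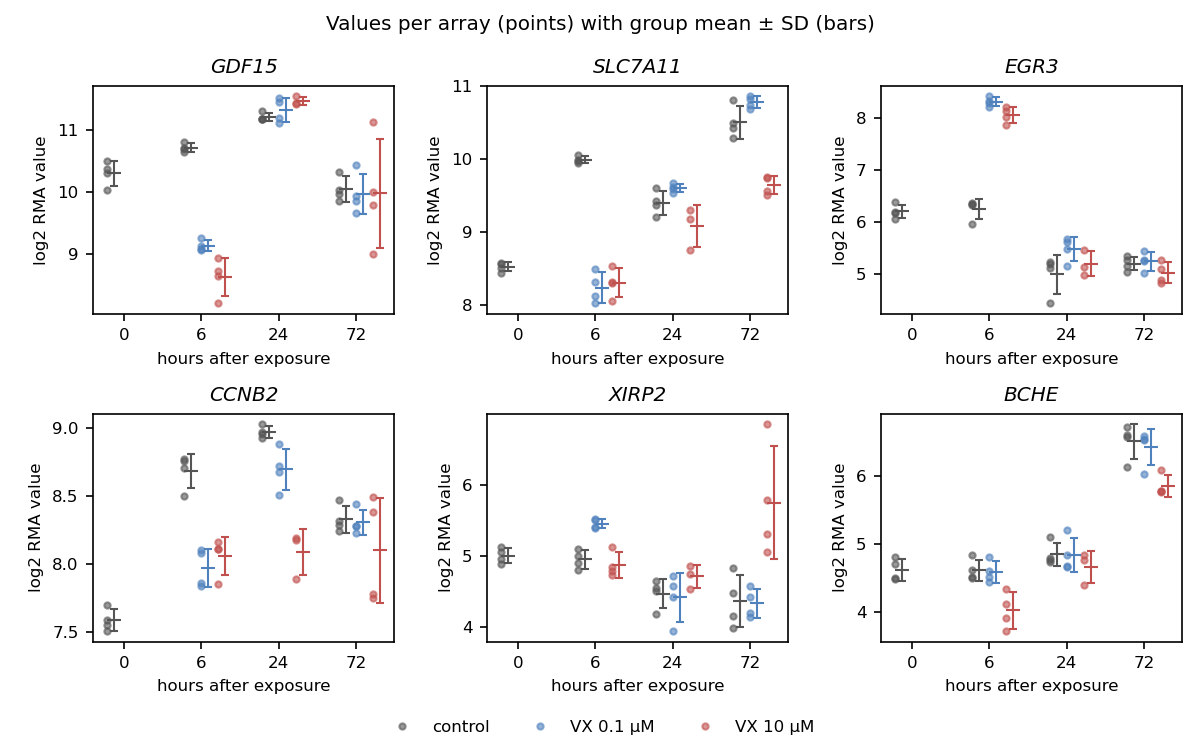
Log2 signal of GDF15, SLC7A11, EGR3, CCNB2, XIRP2 and BCHE against time after exposure, with 1 point per array and unexposed, 0.1 µM and 10 µM cultures marked apart; bars are group means ± SD. GDF15 and SLC7A11 lay below unexposed cultures at 6 h at either dose, and BCHE, near background before 72 h, lay below them at 10 µM at 72 h.

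The 72 h comparisons ask what remained of the response 3 days later. At 0.1 µM, 3297 genes changed (1039 higher, 2258 lower), 45 by 1.5-fold or more, and groups did not overlap in 20.6% of tested genes against 2.86% by chance. SPOCK1, a matrix proteoglycan, rose by 0.60 ± 0.08 (adjusted p = 8.57e-05) and FOLR1, a folate receptor, by 0.88 ± 0.26. PGAM2, muscle phosphoglycerate mutase, fell by 0.94 ± 0.14 (adjusted p = 0.000173), HRC, a histidine-rich calcium-binding protein of the sarcoplasmic reticulum, by 0.87 ± 0.15, and CASQ2 by 0.76 ± 0.13. CACNA1D, a voltage-gated calcium channel subunit, fell by 0.72.

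Matrix genes rose in 17 of 34 cases at 0.1 µM and 72 h and fell in 1, or 19 and 1 over the list alone, with TNC at 0.44, LOX at 0.38 and FN1 at 0.28. Their median was 0.15 (adjusted p = 1.57e-10; adjusted p = 0.0635 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 20 cases and fell in 0, the same over the list alone, ACAT2 by 0.48 and HMGCS1 by 0.36 (median 0.15, adjusted p = 5.42e-06; adjusted p = 0.281 with an estimated correlation). Fibroblast markers rose in 6 of 12 cases and fell in 2, or 7 and 2 over the list alone, COL1A1 by 0.51 and DCN by 0.42 (median 0.20, adjusted p = 0.00545; adjusted p = 0.244 with an estimated correlation). Fatty acid synthesis genes rose in 4 of 16 cases and fell in 1, FASN by 0.40 (median 0.11, adjusted p = 0.0209; adjusted p = 0.278 with an estimated correlation).

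Oxidative phosphorylation genes fell in 17 of 33 cases at 0.1 µM and 72 h, or 21 over the list alone, NDUFV1 by 0.25 and CYC1 by 0.25 (median −0.12, adjusted p = 4.33e-06; adjusted p = 0.505 with an estimated correlation). Sarcomere genes fell in 8 of 23 cases, or 10 over the list alone, TNNI3 by 0.55 and MYOM2 by 0.50 (median −0.12, adjusted p = 0.00322; adjusted p = 0.609 with an estimated correlation). Fatty acid oxidation genes fell in 10 of 29 cases, or 16 with 1 rising over the list alone (median −0.17, adjusted p = 0.00464; adjusted p = 0.505 with an estimated correlation). Histone genes fell in 6 of 11 cases, H1-2 by 0.41 (median −0.31, adjusted p = 0.0418; adjusted p = 0.505 with an estimated correlation). These falls depended on scaling: none of the oxidative phosphorylation genes fell after centring or with the interquartile range as a covariate, and no sarcomere gene fell with that covariate.

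The count at 0.1 µM and 72 h moved with scaling, with single arrays and with the spread estimated from all groups. Fitted on the arrays of the compared groups alone it was far lower, as counted below among the other settings. Residual deviation at 72 h was 0.14 to 0.21 on these exposed arrays and 0.094 to 0.124 on unexposed ones. The balance of calls was 841 higher and 722 lower after quantile normalization, 3003 and 482 after centring, and 85 and 33 with the interquartile range as a covariate. Leaving out exposed replicate 4 lowered the count to 1195, and leaving out unexposed replicate 1, 3 or 4 lowered it to 2004, 2053 or 2104.

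At 10 µM and 72 h, 3031 genes changed (1305 higher, 1726 lower), 182 by 1.5-fold or more, and groups did not overlap in 20.7% of tested genes against 2.86% by chance. XIRP2, an actin-binding protein of intercalated discs, rose from 4.37 ± 0.37 to 5.75 ± 0.80 (1.38 ± 0.22, adjusted p = 5.39e-05). MGP, an inhibitor of calcification, rose by 1.18 ± 0.21, PRIMA1, which anchors acetylcholinesterase to membranes, by 0.90 ± 0.15, and MB, myoglobin, by 0.82 ± 0.10. RGCC, a cell cycle regulator, fell from 8.35 ± 0.43 to 6.12 ± 0.59 (−2.22 ± 0.23, adjusted p = 1.04e-07). GSG1 fell by 1.34 ± 0.14, EMP1, an epithelial membrane protein, by 1.30 ± 0.18, and COL4A4, a basement membrane collagen, by 1.14 ± 0.13. BCHE fell by 0.65 ± 0.14 (adjusted p = 0.00145).

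Sarcomere genes rose in 10 of 23 cases at 10 µM and 72 h and fell in 0, or 11 and 0 over the list alone, with TCAP, the titin cap, at 0.82 and LMOD2 at 0.69. The median was 0.15 (adjusted p = 5.88e-06; adjusted p = 0.399 with an estimated correlation). Genes of the NRF2 oxidative stress response fell in 10 of 28 cases and rose in 0, the same over the list alone, SLC7A11 by 0.86, HMOX1 by 0.83 and NQO1 by 0.51. Their median was −0.11 (adjusted p = 6.64e-05; adjusted p = 0.338 with an estimated correlation). Targets of p53 fell in 10 of 26 cases, the same over the list alone, FAS by 0.46 and RRM2B by 0.24 (median −0.10, adjusted p = 0.00397; adjusted p = 0.346 with an estimated correlation). Apoptosis regulators fell in 9 of 25 cases and rose in 2, the same over the list alone, PMAIP1 by 0.53 and BID by 0.48 (median −0.10, adjusted p = 0.0229; adjusted p = 0.399 with an estimated correlation). Cell cycle genes fell in 9 of 44 cases, UHRF1 by 0.61 (median −0.13, adjusted p = 0.00672; adjusted p = 0.775 with an estimated correlation). The balance of all calls was 2078 higher and 1242 lower after centring, and 841 and 615 with the interquartile range as a covariate. Fitted on the arrays of the compared groups alone the count was far lower, as counted below among the other settings. Residual deviation was 0.138 to 0.194 on these exposed arrays and 0.094 to 0.124 on unexposed ones.

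Across genes, which are not independent replicates, the 72 h changes at the 2 doses correlated at 0.37. Shared controls alone gave 0.5 in simulation and split controls gave 0.27 (0.13 to 0.4), with a covariance of 0.0132 of which 0.00872 was left after the simulated part of 0.00447. Both doses raised 301 genes and lowered 361, and 223 went opposite ways. Independence would give 87 and 251, but noise with shared controls would give 332 and 704. With different control arrays for each dose 20 and 38 were shared, where independence gives 15 and 48, and 92 went opposite ways. The counts of shared genes at 72 h thus did not go beyond what shared controls give. Each dose then had only a pair of control arrays, which limits these counts. The correlation of 0.27 with split controls stayed positive in each split (0.13 to 0.4), which sharing of control arrays alone would not give.

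The direct comparison of doses at 72 h tests those opposite changes. Here 4058 genes differed (2747 higher, 1311 lower at 10 µM), 333 by 1.5-fold or more. With the 8 arrays alone and replicate number as a block, 1678 genes differed (1110 higher, 568 lower), and 1640 of them were in the larger set. The block was used since all 4 pairs passed the minimum correlation, but only 2 of the 4 arrays at 10 µM correlated best with their own number. HRC was higher by 1.65 ± 0.15 (7.99 ± 0.21 at 0.1 µM and 9.64 ± 0.30 at 10 µM, n = 4 each, adjusted p = 1.5e-09), STYXL2, a sarcomere-associated pseudophosphatase, by 1.60 ± 0.13 and TCAP by 1.51 ± 0.18. RGCC was lower by −2.49 ± 0.23 (adjusted p = 2.09e-09), NAV3, a microtubule-binding protein, by −1.23 ± 0.13, and NOX4, which generates hydrogen peroxide, by −1.21 ± 0.20. BCHE was lower by −0.57 ± 0.14 (adjusted p = 0.00243), while PRIMA1 and COLQ, which tether acetylcholinesterase, were higher by 1.01 and 0.79.

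Sarcomere genes were higher at 10 than at 0.1 µM in 18 of 23 cases and lower in 0, with the same counts over the list alone. LMOD2 was higher by 1.26, MYOM2 by 0.97 and MYL2 by 0.65. The median was 0.24 (adjusted p = 2.94e-10, 1.05e-08 with the block; adjusted p = 0.116 with an estimated correlation). Oxidative phosphorylation genes were higher in 27 of 33 cases and lower in 0, the same over the list alone, UQCRC1 by 0.50 and NDUFV1 by 0.40. Their median was 0.16 (adjusted p = 7.36e-10, 2.14e-06 with the block; adjusted p = 0.155 with an estimated correlation). Matrix genes were lower in 19 of 34 cases and higher in 2, or 21 and 2 over the list alone, INHBA by −0.68, TIMP3 by −0.58 and LOX by −0.50. Their median was −0.23 (adjusted p = 1.63e-10, 3.57e-09 with the block and 0.0117 with an estimated correlation).

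Ion channel and calcium handling genes were higher at 10 µM in 16 of 25 cases and lower in 1, or 18 and 1 over the list alone. CASQ2 was higher by 0.73 and JPH2, which couples membranes for calcium release, by 0.47 (median 0.29, adjusted p = 0.000176; adjusted p = 0.116 with an estimated correlation). Cardiac transcription factors were higher in 10 of 17 cases and lower in 0, or 11 and 0 over the list alone, IRX4 by 0.52 and NKX2-5 by 0.44. Their median was 0.32 (adjusted p = 0.000754; adjusted p = 0.155 with an estimated correlation). NRF2 targets were lower in 10 of 28 cases, the same over the list alone, SLC7A11 by −1.14 and GCLM by −0.69 (median −0.10, adjusted p = 8.58e-08; adjusted p = 0.116 with an estimated correlation). The balance of all calls was 2044 higher and 1851 lower after quantile normalization, and 1634 and 2266 after centring.

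Averaging each dose over the 3 times asks which genes differed on average, whether or not they did at each time. At 0.1 µM 5444 genes changed (1598 higher, 3846 lower) and at 10 µM 7259 (2823 and 4436). CASQ2 was lower by −1.01 at 0.1 µM (adjusted p = 2.77e-11) and EGR3 higher by 0.86 (adjusted p = 1.52e-09), with most of the EGR3 value from 6 h (2.07, against 0.48 at 24 h). SLC7A11 was lower by −0.96 at 10 µM (adjusted p = 6.56e-13) and ASPM by −0.83 (adjusted p = 2.76e-10). Cell cycle genes fell in 30 of 44 cases and rose in 0 at 10 µM, or 31 and 0 over the list alone (median −0.34, adjusted p = 1.79e-08; adjusted p = 0.583 with an estimated correlation). The balance of calls became 2234 higher and 2217 lower at 0.1 µM, and 3326 and 3105 at 10 µM, after quantile normalization. After centring it was 4595 and 1474, and 6108 and 2208, and with the interquartile range as a covariate 1031 and 1494, and 810 and 1106.

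Genes past the threshold in the same direction at each of the 3 times were counted as well. At 0.1 µM 8 genes were higher and 143 lower, where 4 and 36 would meet by chance, and at 10 µM 112 were higher and 247 lower, where 6.1 and 39.7 would. In all 6 comparisons with unexposed cultures ZYX, zyxin of focal adhesions, was higher (0.20 to 0.79). The 22 genes lower in all 6 included GSG1 (−0.49 to −1.34), SLC25A20, the stress sensor ERN1, SYNPO2 of the Z-disc and SLC1A3, a glutamate transporter. The comparisons of 1 time share control arrays, so these genes did not have 6 independent tests. The counts over 3 times and over all 6 comparisons were not repeated under other scalings, which changed the balance of calls at single times. Their values by chance take the times as independent. Changes as small as −0.14 (LACTB at 0.1 µM and 72 h) are among the 22.

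Transcripts of acetylcholinesterase, the target of VX, showed no change past the threshold. ACHE lay between 5.95 and 6.17 in all 10 groups and passed no test. BCHE rose in unexposed cultures by 1.88 ± 0.14 between 0 h (4.62 ± 0.16) and 72 h (adjusted p = 3.26e-13), out of the range near background. Its group means at 0, 6 and 24 h all lay under the filter value of 4.88, at 4.03 ± 0.27 to 4.85 ± 0.25, so its expression change after exposure was read at 72 h alone. There it lay at 5.84 ± 0.16 at 10 µM, a fall of 0.65 ± 0.14, and at 6.42 ± 0.26 at 0.1 µM, where it did not pass the test.

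Whether the 10 µM effect itself changed with time was tested as a difference of differences. Between 6 and 24 h it moved in 2102 genes (1353 upward, 749 downward), and between 24 and 72 h 538 genes passed (392 and 146). From 6 to 24 h ECM2 moved by 2.43 and GDF15 by 2.34, the reverse of their falls at 6 h, and EGR3 by −1.61, the reverse of its rise. Divisions of the arrays exchange exposed and unexposed arrays within each time, so they cannot exclude chance for a change of the effect. From 6 to 24 h 2 of 100 divisions, the real one included, gave as many genes, and the highest other gave 2369. From 24 to 72 h 5 of 100 did, and the highest other gave 826. The largest values there included LMOD2 at 1.15, STYXL2 at 1.26 and RGCC at −1.33. The first balance was 1150 upward and 982 downward after quantile normalization and 1008 and 1199 after centring. The second was 318 and 255, 293 and 220, and 475 and 303 with the interquartile range as a covariate, and it fell to 160 genes without exposed replicate 4 at 24 h. It was 347 without unexposed replicate 2 at 24 h, 308 without unexposed replicate 2 at 72 h and 345 without exposed replicate 4 at 72 h.

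The arrays themselves differed in spread. The interquartile range of log2 signal was 4.36 ± 0.04 SD in unexposed cultures at 6 h and 4.19 ± 0.06 at 10 µM (exact permutation p = 0.0286, n = 4 each). At 72 h it was 4.37 ± 0.05 without exposure and 4.16 ± 0.10 at 0.1 µM (exact permutation p = 0.0286). The mean was lower than in unexposed cultures in each of the other 4 exposed groups as well. The differences were −0.17 at 10 µM and 24 h and −0.13 at 10 µM and 72 h (exact permutation p = 0.0571 for each, at 24 h the smallest that 3 against 4 allows), −0.11 at 0.1 µM and 24 h (exact permutation p = 0.114) and −0.02 at 0.1 µM and 6 h (exact permutation p = 0.371). The excess of 3′ over 5′ signal of the ACTB and GAPDH control probe sets, a sign of RNA quality, was 0.56 ± 0.02 at 10 µM and 0.72 ± 0.11 in unexposed cultures at 6 h (exact permutation p = 0.0286, the smallest that 4 against 4 allows). Over the 6 comparisons its Benjamini-Hochberg adjusted p was 0.172. ACTB alone gave a difference of −0.30 and GAPDH alone −0.02. In the other 5 comparisons the difference ranged from −0.07 to 0.12, with exact permutation p from 0.2 to 0.486.

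**Figure D4:**
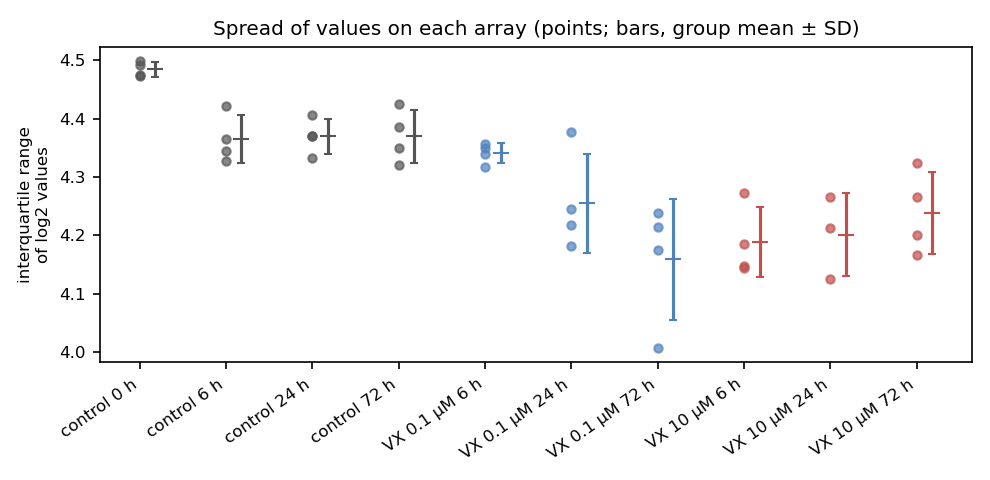
Interquartile range of log2 signal over genes (vertical) of each array by group (horizontal), with 1 point per array, bars for mean ± SD and n = 3 or 4 per group. The mean range was narrower in all 6 exposed groups than in unexposed cultures of the same time, by −0.02 at 0.1 µM and 6 h to −0.21 at 0.1 µM and 72 h.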

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

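Results that stood out by fixed rules are listed first, then technical explanations of 3 patterns and the regrouping of arrays. The tests of handling, of the rise in unexposed cultures and of RNA integrity were chosen only after the results were seen, and so were the interquartile range covariate and the leaving out of 3 deviating arrays as settings.

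Within groups of 4 cultures, an array was picked out when its gap to its nearest neighbour over the group's range passed Dixon's 95% value, which chance alone does in about 1 in 20 groups. Of 54 group and measure pairs, 8 were picked out. Residual deviation was high in unexposed replicate 1 at 6 h (0.153) and in 0.1 µM replicate 4 at 72 h (0.21). Mean log2 signal was set apart in 10 µM replicate 3 at 6 h (6.108) and 10 µM replicate 4 at 72 h (6.171), and the 3′ minus 5′ measure in unexposed replicate 3 at 72 h (0.68). BCHE lay apart in unexposed replicate 2 at 24 h (5.103), 0.1 µM replicate 4 at 72 h (6.03) and 10 µM replicate 1 at 72 h (6.079). Of 538 named genes, 23, 43, 21 and 32 had an array set apart in unexposed cultures at 0, 6, 24 and 72 h. At 0.1 µM 13, 32 and 33 had one at 6, 24 and 72 h, and at 10 µM 30 at 6 h and 19 at 72 h.

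The effect of 10 µM differed between 6 and 24 h in 2102 genes. It moved upward most in ECM2 (2.426), GDF15 (2.344), ESM1 (1.636), SLFN5 (1.628) and PRDM16 (1.574), and downward most in RGCC (−1.857), EGR3 (−1.607), VGLL3 (−1.569), SETBP1 (−1.366) and HECW2-AS1 (−1.354). HECW2-AS1 lay near background (under 4.88) at 24 h in both groups, so the size of its value is uncertain. Between 24 and 72 h 538 genes passed the threshold, and for neither count could divisions of the arrays exclude chance. ABRA (1.645), STYXL2 (1.257), SLCO5A1 (1.249), LMOD2 (1.147) and XIRP2 (1.144) moved upward most. EMP1 (−1.358), RGCC (−1.333), DNER (−1.068), MAP3K7CL (−0.982) and ECM2 (−0.928) moved downward most. XIRP2 lay near background at 24 h in both groups and in unexposed cultures at 72 h, so the size of its value is uncertain too.

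Probe sets without exactly 1 gene symbol, with none or several, were left out of the gene tests. Of 6188 such probe sets above the expression filter, 1070 and 1467 passed the threshold at 6 h (0.1 and 10 µM), 396 and 560 at 24 h, and 1011 and 622 at 72 h.

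The first pattern is the lower stress response list at 6 h after both doses, with medians of −0.53 and −0.39. With each array's interquartile range as a covariate the median at 10 µM was −0.38 (SE 0.09), and 22 genes of the list still fell, so narrower array spread does not account for it. The recorded protocol gives unexposed cultures the same 1 h step and 3 washes, without saying whether their timing matched. Handling shared by exposed dishes alone would leave the doses alike. At 6 h 7 of the 31 genes (22.6%) differed between doses, beside 2751 of all 15518 genes tested. The exact interval of 9.59% to 41.1% takes the genes as independent, and genes of a list can vary together. These genes are too few to decide, so the effect of handling and that of VX cannot be told apart. The unexposed cultures themselves rose by a median of 0.33 (SE 0.08) between 0 and 6 h, and medians of exposed cultures at 6 h lay below unexposed ones at 0 h (−0.15 and −0.12), with 13 genes lower and 1 higher at 0.1 µM, and 10 lower and 7 higher at 10 µM. A rise that exposed cultures did not share is thus consistent with part of the pattern and not with genes such as GDF15, which lay at 10.30 at 0 h, 10.71 in unexposed cultures at 6 h and 8.63 at 10 µM.

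The second pattern is the higher sarcomere list at 10 than at 0.1 µM and 72 h, with a median of 0.24 (SE 0.11). A lower share of cardiomyocytes at 0.1 µM would put the marker lists of other cell types lower at 10 µM by similar amounts. Their medians were −0.18 for fibroblast, −0.15 for smooth muscle, −0.04 for endothelium and −0.09 for neural markers. By camera their adjusted p-values were 0.053, 0.129, 0.505 and 0.134 in the full model. On the arrays of the 2 doses alone, with replicate number as a block, they were 0.0223, 0.283, 0.534 and 0.0465. The largest difference between any 2 of these medians was 0.88 standard errors, so a changed mixture and a change within cardiomyocytes cannot be told apart. With the interquartile range as a covariate the median was 0.23, and without the 3 arrays with large deviations it was 0.25 with 16 of 23 genes higher, so neither of these accounts for it.

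The third pattern is that long genes were lower after 10 µM, where over 15494 genes with a length in GRCh38.p14 the rank correlation of length with change was −0.20 at each time, against −0.08, −0.07 and −0.14 at 0.1 µM. At 6 h 1404 of the longest 3874 genes were lower and 357 higher, against 538 and 523 of the shortest. With expression level taken out, the correlation was −0.14 at its weakest, so expression level does not account for it by itself. Poorer RNA integrity would raise the 3′ minus 5′ measure, but its differences of −0.16, −0.07 and 0.07 at 6, 24 and 72 h went both ways, and the lowest rested on ACTB (−0.30) more than GAPDH (−0.02), with a Benjamini-Hochberg adjusted p of 0.172. With the interquartile range as a covariate the correlation shrank to −0.09, −0.04 and −0.10, so narrower array spread, RNA integrity and an effect on long genes cannot be told apart.

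The number of changed genes was also set beside other ways of dividing the same arrays into groups. For the 6 comparisons with unexposed cultures the real division ranked 1 of 35. At 6 h it gave 4465 (0.1 µM) and 5580 (10 µM) against at most 5 and 6 otherwise. At 24 h it gave 1949 and 2086 against at most 368 and 794, and at 72 h 3297 and 3031 against at most 585 and 602. A share of 1 in 35 is under 0.05 in each. It is the smallest that 35 divisions allow, and was not adjusted over the 6 comparisons. Between doses the real counts of 2751, 1075 and 4058 at 6, 24 and 72 h exceeded the highest others of 7, 305 and 1944. At 72 h the 1944 came from a division that kept a pair of equal replicate number together. The real division is among the 8 that part every pair, and the highest of the others there was 276. The unexposed comparisons with 0 h had at most 2 genes in any other division.

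For the averages over time, 100 divisions were tried and the real one ranked 1 in each. The highest other counts were 859 against 5444 at 0.1 µM, and 5230 against 7259 at 10 µM. For the change of the 10 µM effect from 6 to 24 h the real 2102 ranked 2 of 100, a share of 0.02, with another division at 2369. These divisions exchange exposed and unexposed arrays within each time. They bear on whether exposure had any effect and cannot decide whether that effect changed with time. From 24 to 72 h the real 538 ranked 5 of 100, with another at 826, and this cannot decide it for the same reason.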

How the results depend on the processing

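Each result was refitted under other settings; the interquartile range covariate, leaving out 3 doubted arrays, the compared groups alone with a block, and single arrays left out of the RNA quality measure were chosen after the data were seen. All probe sets raised the counts because more units were tested. They gave 8694 and 10690 probe sets, not genes, at 6 h (0.1 and 10 µM), 3086 and 3904 at 24 h, and 6468 and 5309 at 72 h. For doses at 6 and 72 h they gave 5054 and 6786, for the averages 10289 and 14924, for the effect from 6 to 24 h 3544, and for unexposed cultures 11896, 12230 and 15964 at 6, 24 and 72 h. For the following counts of genes the cause was not tested unless stated. Array weights gave 3540 and 3950 at 24 h (0.1 and 10 µM), 4172 and 2091 for doses at 6 and 24 h, and 3439 for the effect from 6 to 24 h. The compared groups alone, with fewer arrays, gave 981 at 0.1 µM and 24 h, 767 and 1397 at 72 h (0.1 and 10 µM), 25 and 1357 for doses at 24 and 72 h, and 107 for the effect from 24 to 72 h. With a replicate block as well, doses at 72 h gave 1678, and the mean of probe sets gave 328 for the effect from 24 to 72 h. At 0.1 µM and 72 h quantile normalization gave 1563 and leaving out doubted arrays 1804. The interquartile range covariate gave 3523 and 718 at 10 µM (6 and 24 h), 118 and 1456 at 72 h (0.1 and 10 µM), 712 for doses at 6 h, and 2525 and 1916 for the averages. Of 43 list calls for exposed cultures and 33 for unexposed times, an estimated correlation kept 0 and 9, and fry called 78 and 70. The RNA quality difference at 10 µM and 6 h was −0.024 with GAPDH alone and −0.058 as 3′ minus middle. Leaving out 1 array gave 1231 to 2387 and 636 to 2279 at 24 h (0.1 and 10 µM), 1195 to 3651 and 2168 to 3228 at 72 h, and 3880 to 4229 and 4620 to 5434 at 6 h. Doses ranged over 1885 to 2751, 199 to 983 and 3385 to 4141 at 6, 24 and 72 h, averages over 4741 to 5806 and 6342 to 7493, and effects over time over 1646 to 1967 and 160 to 642. Unexposed times ranged over 5641 to 6053, 5662 to 5836 and 7436 to 7560, and list calls over 39 to 46 and 32 to 36. RNA quality at 10 µM and 6 h ranged from −0.194 to −0.106, and no 3 against 4 arrays can reach an exact p of 0.05. The mean of probe sets reversed SQLE (0.079) and MYLK (0.005) at 0.1 µM and 6 h, COX7B (0.04) at 10 µM and 6 h, CHORDC1 (−0.049) at 0.1 µM and NDUFA2 (0.006) at 10 µM and 24 h, and ACACB (−0.138) at 0.1 µM and 72 h. It reversed TP53INP1 (0.014) and SC5D (0.01) for doses at 6 h, TBX3 (0.002), ACACB (−0.15, adjusted p = 0.000585), NDUFA2 (0.026) and CLOCK (0.016) in the 0.1 µM average, and TBX3 (0.006) and CLOCK (0.022) in the 10 µM average. In unexposed cultures it reversed MEF2A (0.111) at 6 h, RPS12 (0.084) at 24 h, and COX4I1 (−0.04) and RPS12 (0.023) at 72 h. The interquartile range covariate reversed RORA (0.017) at 10 µM and 24 h. At 0.1 µM and 72 h it reversed XAGE-4 (−0.1), LCE1E (−0.024), MRNIP-DT (0.089), GNAI2 (−0.018), ABCC3 (−0.026), GPAM (0.126) and LIN28B (0.04). In the averages it reversed HSPA4L (0.039), GPAM (0.023) and H2AC6 (0.013) at 0.1 µM, and HSPA4L (0.011), CXCL11 (0.014), TEK (−0.03) and CD34 (−0.009) at 10 µM. Of 29749 other values of named genes 27370 stayed the same, 2345 were weaker, 1 was stronger and 33 reversed. Most of these, 16637, came from leaving out 1 array. With the interquartile range covariate 1195 of 1630 stayed the same, 419 were weaker, 1 was stronger and 15 reversed. With the compared groups alone 296 of 1630 were weaker. Of 4279 list values 3984 stayed the same, 157 were stronger and 138 weaker.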

Other observations

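The cholinergic signalling list, which includes ACHE and BCHE, was not called as a list after exposure. Of 16 genes measured, 2 rose and 1 fell at 0.1 µM and 6 h, 4 and 4 at 10 µM and 6 h, 1 and 1 at 0.1 µM and 24 h, 2 and 1 at 10 µM and 24 h, 1 and 1 at 0.1 µM and 72 h, and 2 and 1 at 10 µM and 72 h. The smallest adjusted p of the list was 0.168. At 10 µM and 6 h its median was 0.01 and its mean −0.09. KCNJ5, an acetylcholine-gated potassium channel subunit, fell by 1.06 and COLQ by 0.71, while RGS4, which shortens muscarinic signalling, rose by 0.49. In unexposed cultures 8 genes of the list rose and 1 fell between 0 and 72 h (median 0.21, adjusted p = 0.0382; adjusted p = 0.0924 with an estimated correlation). Other serine hydrolases, which organophosphates also bind, rose in 5 of 18 cases and fell in 2 at 10 µM and 72 h, CES2 by 0.53 and PREP by 0.39, and the smallest adjusted p of that list was 0.108.

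In unexposed cultures several cell-type lists moved with time. Fibroblast markers rose in 8 of 12 cases at 6 h (median 0.65, adjusted p = 3.29e-07, and 0.000504 with an estimated correlation), with POSTN at 2.14 and COL6A3 at 1.94, and stood at medians of 0.73 and 1.08 at 24 and 72 h. All 10 smooth muscle markers rose at 6 and 24 h (medians 0.42 and 0.47), MYLK by 0.75 and CALD1 by 0.65 at 6 h. Inflammatory genes rose in 7 cases and fell in 2 at 6 h, LIF by 1.88 and TNFAIP3 by 1.56 (median 0.17, adjusted p = 5.18e-05, and 0.00294 with an estimated correlation). Oxidative phosphorylation and fatty acid oxidation genes fell at 6 h in 25 of 33 and 19 of 29 cases, with 0 and 2 rising (medians −0.16 and −0.26; adjusted p = 0.367 and 0.26 with an estimated correlation). Ribosomal protein genes fell in 16 of 34 cases at 72 h (median −0.09, adjusted p = 0.00511; adjusted p = 0.418 with an estimated correlation).

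Lists called in exposed cultures but not described above were small shifts. At 0.1 µM and 24 h smooth muscle markers fell in 4 of 10 cases (median −0.09, adjusted p = 0.0474; adjusted p = 0.399 with an estimated correlation) and neural markers rose in 3 of 11 (median 0.10, adjusted p = 0.0388; adjusted p = 0.278 with an estimated correlation). Cardiac transcription factors fell in 2 of 17 cases (median −0.14, adjusted p = 0.0418; adjusted p = 0.6 with an estimated correlation), cell cycle genes in 1 of 44 (median −0.12, adjusted p = 0.0323; adjusted p = 0.853 with an estimated correlation). Matrix genes rose in 4 cases and fell in 2 (median 0.05, adjusted p = 0.0293; adjusted p = 0.505 with an estimated correlation). At 0.1 µM and 72 h smooth muscle markers rose in 4 cases and fell in 1 (median 0.10, adjusted p = 0.0445; adjusted p = 0.399 with an estimated correlation), and immediate early genes rose in 3 of 25 (median 0.06, adjusted p = 0.018; adjusted p = 0.545 with an estimated correlation). At 10 µM and 72 h oxidative phosphorylation genes rose in 4 of 33 cases (median 0.05, adjusted p = 0.0229; adjusted p = 0.775 with an estimated correlation).

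The remaining lists had no call against unexposed cultures of the same time. At 10 µM and 72 h cardiac stress and natriuretic peptide genes rose in 6 of 14 cases and fell in 2 (median 0.14, smallest adjusted p 0.105). Glycolysis and hypoxia genes fell in 10 of 31 cases at 0.1 µM and in 9 at 10 µM at 6 h (smallest adjusted p 0.186). Of 21 interferon genes at most 5 fell and 3 rose in any comparison (0.248), of 15 circadian clock genes 3 and 3 (0.475), of 13 glucocorticoid response genes 3 and 3 (0.134), and of 11 epithelial markers 4 and 2 (0.267). Among 10 endothelial, 10 pluripotency and 8 endoderm and liver markers, at most 2 genes rose and 2 fell in any comparison, with smallest adjusted p of 0.0856, 0.336 and 0.107.

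Differences between doses reached further lists. At 6 h oxidative phosphorylation genes were lower at 10 µM in 10 of 33 cases (median −0.11, adjusted p = 2.89e-05; adjusted p = 0.585 with an estimated correlation), and fatty acid oxidation genes in 14 of 29 (median −0.17, adjusted p = 4.28e-05; adjusted p = 0.338 with an estimated correlation). Ion channel genes were lower in 9 of 25 cases (median −0.15, adjusted p = 0.00206; adjusted p = 0.338 with an estimated correlation), and matrix genes higher in 10 of 34 and lower in 1 (median 0.11, adjusted p = 0.00175; adjusted p = 0.338 with an estimated correlation). At 24 h oxidative phosphorylation genes were higher in 3 cases, or 8 over the list alone (median 0.09, adjusted p = 3.59e-08; adjusted p = 0.224 with an estimated correlation). At 72 h fatty acid oxidation genes were higher in 17 of 29 cases (median 0.21, adjusted p = 0.000176; adjusted p = 0.155 with an estimated correlation). Cholesterol synthesis genes were lower in 11 of 20 cases and higher in 2 (median −0.21, adjusted p = 9.6e-05; adjusted p = 0.155 with an estimated correlation).

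No 2 arrays were identical. Correlations between arrays of a group were 0.9943 to 0.9987, and between groups 0.9785 to 0.9979. Reading the raw intensities would show whether the narrower spread of some exposed arrays arose before or after normalization.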
